A study of Mus musculus with 12 samples.

How the data were processed

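The samples were scrapings of the fundic mucosa of mice in 4 groups: wild type, gastrin knockout infused with saline, gastrin knockout infused with gastrin, and double knockout of gastrin and CCK. Per the labels, about 1 µg of total RNA per sample was isolated with Trizol and a column kit, labelled with biotin and hybridised to a one-colour short-oligonucleotide array. There were 12 arrays, 3 per group, and all 12 columns of the table were used.

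The deposited table holds 1 intensity per probe set and array, on a linear scale, in whole numbers of which some are below 0. The array medians were alike. Whether and how the authors scaled the intensities, and the method of probe-set summary and background treatment, are not given in the sources used here. Of 22690 probe sets, 64 controls were taken out before testing, which left 22626. Of these, 20380 had 1 gene symbol, 691 had several and 1555 were not in the probe table, and the symbols came to 12393 distinct genes. The gene identifiers of 20351 probe sets were matched in the gene table of mouse assembly GRCm38.p6, which changed 0 symbols and served only for names and gene order.

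Because the medians lay between 403 and 421, no further scaling was applied. Values under 16 were raised to 16 and log2 values taken. Between 7.57% and 8.47% of the values on an array were under 16, and 411 probe sets were at or below it on all 12 arrays. Group means are of deposited intensities, with the SD between arrays. The noise level of an array was its lowest percentile (1) with the sign turned, and group means of it lay between 75.3 and 90.7. Where all values of a group, or their mean, lay within the noise, the fold change is given as a bound, from the higher of the noise level and the value on each array of the dim group.

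One model with a mean per group was fitted to each probe set over all 12 arrays (limma 3.58.1 in R 4.3.3, empirical Bayes moderation, 8 residual and 1.10 prior degrees of freedom). The 5 comparisons were contrasts of this model, with the Benjamini-Hochberg adjustment over 22626 probe sets and a threshold of adjusted p under 0.05. Infusion differs along with genotype in 3 of the 5, those of an infused with an uninfused group. The comparisons share arrays and are not independent of one another. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

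For gene lists the camera test of limma was used, with its preset inter-gene correlation of 0.01, on 25 lists of 340 genes, 303 of them measured, taking the probe set with the highest mean for each gene. Adjustment was over the 25 lists of a comparison. Members were also counted after adjustment over all probe sets and adjusted over the list alone. The test was repeated with a correlation estimated from the data. The lists cover parietal, chief, surface mucous, mucous neck, enterochromaffin-like and other endocrine cells, genes reported to respond to gastrin, proliferation, interferon response, antigen presentation, B and plasma, T and natural killer, myeloid and mast cells, stroma and smooth muscle, forestomach, pancreas, intestine, fat, blood, oxidative phosphorylation, sterol synthesis, endoplasmic reticulum folding, immediate early and heat shock genes, and sex. Lists, comparisons, tests and the rule for naming genes were fixed before the data were examined.

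The rule for naming genes took, in each comparison, probe sets past the test with 1 symbol, with the mean of the brighter group at or above the median of all probe sets, and with no overlap between the groups. Of these the 12 largest rises and the 12 largest falls were named, 1 probe set per gene. Gast, Cck and list members could be named whatever their result, and overlap counts name up to 10 probe sets with the largest smaller change. Overlap counts were set beside 100 simulated unchanged sets that shared arrays in the same way and beside the count for independent lists.

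The test was tried on simulated data in which 200 of 22626 probe sets were changed, in 5 runs per comparison. The 200 were drawn only from probe sets with a mean at or above the median, so recovery of dimmer ones was not tried. At 1.5-, 2-, 3- and 4-fold it recovered 28.8%, 74.4%, 95.6% and 97.6% for the saline-infused knockout against wild type, and 29.2%, 73.6%, 95.2% and 98.8% for gastrin against saline infusion. For the double knockout it recovered 32%, 75.2%, 93.6% and 98.4% against wild type and 32.8%, 76%, 94% and 96.8% against the saline-infused knockout. For the gastrin-infused knockout against wild type it recovered 34.8%, 73.2%, 94.4% and 96.4%. False calls were 6.20%, 4.01%, 6.85%, 7.07% and 5.44% of calls, in the same order. Lists shifted by 0.3 on the log2 scale passed camera in 80%, 86.7%, 86.7%, 93.3% and 93.3% of 15 runs, and unshifted ones in 0%. The simulated genes were independent, which real genes are not.

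The alternatives were quantile normalization, centring each array on its median, a filter keeping probe sets at or above the median, floors of 1 and 64, trend and robust options of the moderation, the replicate number as a block, only the arrays of the 2 groups compared, a plain test per probe set, a change of at least 1.5-fold as well, camera with an estimated correlation, the mean of a gene's probe sets in place of the brightest, and each array left out in turn. Added after the data were seen were the ratio of the 3' to the 5' Gapdh control or the forestomach markers as a covariate, and fits without the double-knockout arrays, without the wild-type arrays of high Gapdh ratio, or without the 2 arrays with smooth muscle or fat markers.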

Results

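Total RNA from scrapings of the fundic mucosa, the acid-secreting lining of the mouse stomach, was measured on 12 one-colour oligonucleotide arrays in 4 groups of 3. The groups were wild-type mice, gastrin knockout mice infused with saline, gastrin knockout mice infused with gastrin, and mice lacking both gastrin and cholecystokinin (CCK). Each infusion lasted 1 week. The labels give an age, 2 months, only for the saline-infused knockouts. The wild-type and double-knockout mice were not described as infused, so infusion is part of every comparison that sets them against an infused group. Each wild-type sample pooled about 2 to 4 mice per the labels, which do not say that the samples of a group came from separate animals. The p-values therefore measure only the spread between these samples, which may be technical. A probe set is a group of short probes for one transcript, and its value is an intensity in the arbitrary units of the deposited table. The array medians lay between 403 and 421. Between 5.52% and 6.43% of the values on an array were below 0. Replicates correlated across probe sets at r between 0.955 and 0.983 on the log2 scale. The number of arrays limits the precision. All fold changes are log2 values, given with standard errors from limma, with 3 arrays on each side.

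Gast, which encodes gastrin, read 579 ± 253 (SD, n = 3) in wild type, with single values of 596, 318 and 823. It read 20 ± 24.4 in the saline-infused knockout, -49.7 ± 19.9 in the gastrin-infused knockout and -87 ± 66.6 in the double knockout (n = 3 each). The highest value on any of the 9 knockout arrays was 37. The log2 fold change against wild type was -4.35 ± 0.36 (adjusted p = 0.00236) in the saline-infused knockout, -5.07 ± 0.36 (adjusted p = 0.00146) in the gastrin-infused knockout and -5.07 ± 0.36 (adjusted p = 0.000547) in the double knockout. Because the knockout values lay within the noise, the measured difference is stated as a bound: at least 5.94-fold, 6.06-fold and 7.18-fold lower, in the same order. Gastrin given by infusion brings no Gast transcript, and none was measured. Cck read 54.3 ± 40.9 in wild type, 59 ± 17.3 in the saline-infused knockout, 43.7 ± 64.1 in the gastrin-infused knockout and 74.7 ± 48.4 in the double knockout (n = 3 each). These values lie near the noise in all 4 groups, so the Cck probe set checks nothing about the double knockout.

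The comparison of the saline-infused gastrin knockout with wild type asked what differs in the fundus without gastrin. Hdc, the enzyme that makes histamine, read -59.3 ± 26.9 against 531 ± 140 in wild type on one of its 2 probe sets, at least 5.73-fold lower (log2 fold change -5.02 ± 0.20, adjusted p = 9.76e-06). The saline-infused values lay within the noise, so the floor largely sets this log2 value. The brighter probe set of Hdc read 102 ± 98.3 against 601 ± 164, with a log2 fold change of -3.06 ± 0.85 that did not pass (adjusted p = 0.107). Chga, which encodes the secretory granule protein chromogranin A, fell from 7800 ± 2214 to 2088 ± 42.9 (-1.86 ± 0.21, adjusted p = 0.00898). Sst, which encodes the acid-inhibiting hormone somatostatin, fell from 18659 ± 4457 to 6689 ± 1310 (-1.47 ± 0.20, adjusted p = 0.0132).

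Among 22626 probe sets tested in this comparison, 470 passed, 160 higher and 310 lower, and they named 397 genes. The adhesion protein vitronectin, Vtn, fell on both of its probe sets (-2.18 ± 0.26, adjusted p = 0.00988), as did Ccn3, a matricellular protein (-1.49 ± 0.18, adjusted p = 0.0101). Ppp1r3c, a glycogen-targeting subunit of protein phosphatase, changed by -1.79 ± 0.19 (adjusted p = 0.0077, 1 of 2 probe sets) and the glycogen synthase gene Gys1 by -1.55 ± 0.25 (adjusted p = 0.0227, 1 of 2). The neuroendocrine protein gene Resp18 fell by 1.70 ± 0.34 on the log2 scale, and the protease gene Bace1 by 1.53 ± 0.30 on 1 of its 4 probe sets. Ybx1, for a nucleic-acid binding protein, changed by -1.51 ± 0.26 on 1 of its 2 probe sets and Adssl1, for an adenylosuccinate synthase, by -1.48 ± 0.26. One probe set of the aspartic protease gene Ctse changed by -1.71 ± 0.35, while its far brighter probe set read 61090 against 59392 and did not pass. On the rising side, Clca1, which encodes a secreted protein of mucous cells, went from 1665 ± 587 to 9283 ± 2200 (2.50 ± 0.42, adjusted p = 0.0258) on 1 of its 2 probe sets. Pigr, the receptor that carries immunoglobulin across epithelia, rose on both of its probe sets (1.82 ± 0.27, adjusted p = 0.0168). The beta-globin gene Hbb-b2 rose by 1.76 ± 0.25 (1 of 2 probe sets), the RNA-binding protein gene Rbm47 by 1.46 ± 0.27 (1 of 2) and the carotenoid oxygenase gene Bco2 by 1.35 ± 0.16. Smaller rises were those of the spliceosome gene Snrpd3 (1.27 ± 0.19, 1 of 3 probe sets), the kinase gene Stk25 (1.27 ± 0.16) and the galectin gene Lgals3 (1.18 ± 0.23). Ly6d, a surface protein of squamous epithelium, rose by 1.15 ± 0.24, the iron reductase gene Cybrd1 by 1.04 ± 0.13, the disulfide isomerase gene Pdia4 by 1.03 ± 0.16 (1 of 2 probe sets) and the epithelial transcription factor gene Ehf by 0.92 ± 0.13 (1 of 3). Of 23 of these genes besides Gast, 9 passed whichever array was left out: Hdc, Chga, Vtn, Ccn3, Ppp1r3c, Hbb-b2, Bco2, Stk25 and Cybrd1. Leaving out wild-type replicate 1, 2 or 3 ended 8, 14 and 10 of the 23 calls, and leaving out saline-infused replicate 1, 2 or 3 ended 11, 11 and 9. The highest adjusted p was 0.14, without wild-type replicate 2. Among 141 bright called genes with more than one probe set, 18 had another probe set called the same way and 33 had another of opposite sign.

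Of 25 gene lists, 4 passed the list test in the saline-infused knockout. The 17 parietal cell genes were lower (median -0.15, adjusted p = 0.0274, and adjusted p = 0.749 with an estimated correlation). Of these, 4 fell and 13 did not pass, and 7 were lower adjusted over the list alone. The 4 were Kcnq1 (-1.32 ± 0.24, adjusted p = 0.0301) and Kcne2 (-0.88 ± 0.13, adjusted p = 0.0191), which form the potassium channel of the acid-secreting cell, Atp4a, the catalytic subunit of the proton pump (-0.66 ± 0.11, adjusted p = 0.0256), and the anion exchanger gene Slc4a2 (-0.62 ± 0.13, adjusted p = 0.0472). Atp4b, the other pump subunit, read 59947 ± 4473 against 78267 ± 9085 (-0.38 ± 0.09, adjusted p = 0.0681). Cckbr, the gastrin receptor gene, read 305 ± 68.5 against 597 ± 95.6 (-0.98 ± 0.22, adjusted p = 0.0582) on its brighter probe set. On the other it read 459 ± 55.8 against 454 ± 130 (0.06 ± 0.28, adjusted p = 0.962). The parietal call was lost without wild-type replicate 3 (median -0.08, adjusted p = 0.106) and without saline-infused replicate 3 (median -0.03, adjusted p = 0.124), while the median was -0.26 without wild-type replicate 2 and -0.29 without saline-infused replicate 1. The 24 genes of oxidative phosphorylation and the citric acid cycle were lower (median -0.16, adjusted p = 0.0311, and adjusted p = 0.749 with an estimated correlation). The only member of that list to pass, Uqcrc2 of respiratory complex III, rose (0.39 ± 0.06, adjusted p = 0.0159, 1 of 2 probe sets), and 23 did not pass. That list's call was lost without wild-type replicate 2 (median -0.09, adjusted p = 0.319), saline-infused replicate 1 (adjusted p = 0.0846) and saline-infused replicate 3 (adjusted p = 0.189).

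The 15 interferon response genes were higher in the saline-infused knockout (median 0.71, adjusted p = 0.000356, and adjusted p = 0.749 with an estimated correlation). Of these, 2 rose and 13 did not pass, with the same 2 adjusted over the list alone. The guanylate-binding protein gene Gbp2 rose from 93.7 ± 28 to 311 ± 155 (1.66 ± 0.35, adjusted p = 0.0483, 1 of 2 probe sets), and the transcription factor gene Irf1 rose from 2091 ± 199 to 3462 ± 387 (0.73 ± 0.15, adjusted p = 0.0491). Ifit1, an antiviral protein gene, read 5099, 1355 and 1316 on the 3 saline-infused arrays and between 529 and 806 in wild type, and did not pass (1.61 ± 0.56, adjusted p = 0.176). Without saline-infused replicate 1 the list's median was 0.24 (adjusted p = 0.00989). The 14 genes of stroma and smooth muscle, all on the lower side, gave a median of -0.59 (adjusted p = 0.0274, and adjusted p = 0.749 with an estimated correlation), and none passed alone. Sparc, a collagen-binding matrix protein gene, read 777 ± 337 against 2443 ± 303 (-1.75 ± 0.46, adjusted p = 0.094). That list's call was lost without wild-type replicate 3 (adjusted p = 0.106), saline-infused replicate 1 (adjusted p = 0.0846) and saline-infused replicate 2 (median -0.34, adjusted p = 0.203).

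Among the lists that did not pass, the enterochromaffin-like and secretory granule list had a median of -0.11 (adjusted p = 0.123). Of its 11 genes 1 fell, Chga, and 4 were lower adjusted over the list alone. Chgb, which encodes chromogranin B, read 516 ± 133 against 1246 ± 590 (-1.21 ± 0.39, adjusted p = 0.155). The chief cell list had a median of -0.06 (adjusted p = 0.196), although Bhlha15, a transcription factor of the mature chief cell, read 1087 ± 118 against 2154 ± 284 (-0.98 ± 0.22, adjusted p = 0.0595). The medians of the surface mucous, mucous neck, proliferation and antigen presentation lists were 0.13, -0.06, 0.25 and 0.14 (adjusted p = 0.112, 0.937, 0.112 and 0.111). Those of B and plasma cells, T and natural killer cells, mast cells, intestinal epithelium, fat and blood were -0.12, 0.27, 0.15, -0.16, -0.19 and 0.42 (adjusted p = 0.937, 0.472, 0.507, 0.507, 0.866 and 0.112). Within the mast cell list, Kit fell by 0.56 ± 0.08 on 1 of its 2 probe sets, a receptor also carried by other cells. The endoplasmic reticulum folding list (median -0.16, adjusted p = 0.742) and the sex list (0.19, adjusted p = 0.409) did not pass either. Median, mean and test differed in sign for other endocrine cells (median 0.33, adjusted p = 0.924), genes reported to respond to gastrin (0.05, adjusted p = 0.924), myeloid cells (-0.02, adjusted p = 0.789), pancreas (0.01, adjusted p = 0.924), sterol synthesis (0.08, adjusted p = 0.937) and immediate early genes (-0.04, adjusted p = 0.789). In the list of genes reported to respond to gastrin, Tgfa, a growth factor, read 1535 ± 198 against 904 ± 80.1 (0.76 ± 0.16, adjusted p = 0.0533), the opposite side from Chga. Within the pancreas list the lipase-related gene Pnliprp1 fell by 0.93 ± 0.12 on the log2 scale, and within the immediate early list Junb rose by 0.86 ± 0.17.

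The squamous forestomach adjoins the fundus in the mouse, and its 12 markers had a median of 0.83 in the saline-infused knockout against wild type that did not pass (adjusted p = 0.123). The keratin gene Krt13 read 5391, 1171 and 4370 on the saline-infused arrays against 1453, 666 and 462 in wild type. The ratio of the 3' to the 5' Gapdh control, a sign of RNA integrity or of target synthesis, was 1.5 ± 0.51 (SD, n = 3) in wild type, up to 2.00, and 1.10 ± 0.08 in the saline-infused knockout. With that ratio as a covariate 47 probe sets passed in place of 470, and without both wild-type arrays of high ratio 77 passed. Leaving out wild-type replicate 1, 2 or 3 gave 285, 94 and 227 calls, and leaving out saline-infused replicate 1, 2 or 3 gave 124, 193 and 212. The groups did not overlap for 22.6% of probe sets, where chance gives 10%. The hybridisation control BioC-5 read 4435 to 5619 in wild type and 5967 to 7472 in the saline-infused knockout. A batch of arrays is therefore not excluded here.

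**Figure D1:**
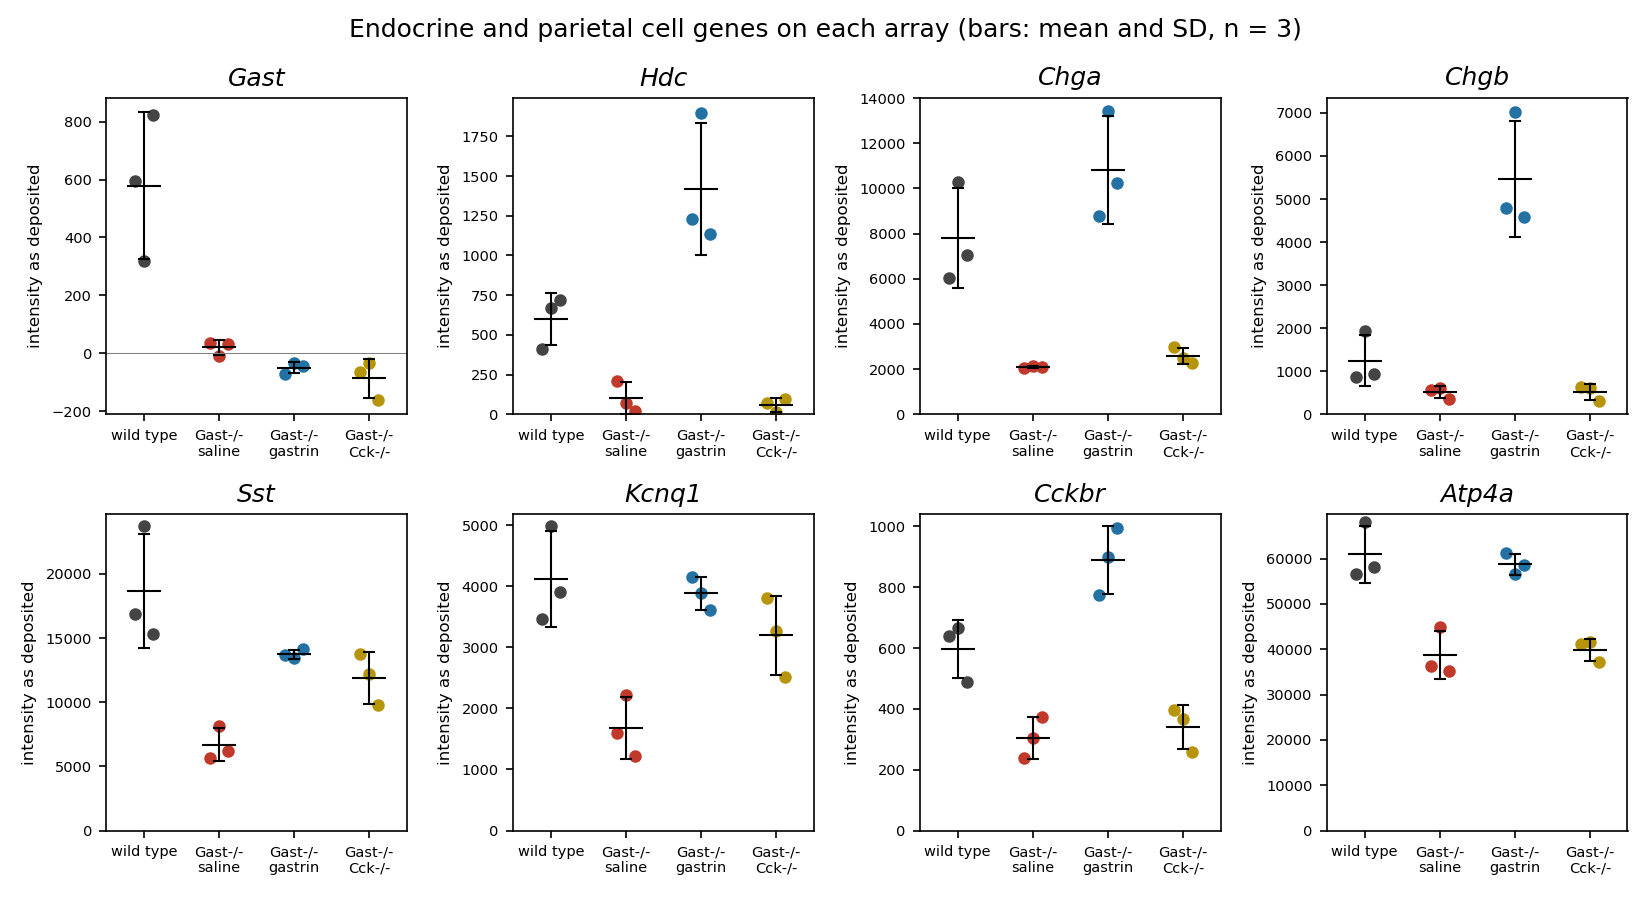
Intensity of Gast, Hdc, Chga, Chgb, Sst, Kcnq1, Cckbr and Atp4a on each of the 12 arrays by group, in deposited units; points are arrays and lines are the mean ± SD (n = 3). Chga has means of 7800, 2088 and 10811 in wild type, saline-infused and gastrin-infused knockout, and Hdc is its brighter probe set, with means of 601, 102 and 1420.

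Gastrin infusion of the knockout, against saline infusion, asked what replacement of the hormone changes, with both arms infused. Hdc went from the noise to 1514 ± 367, at least 16.4-fold higher (log2 fold change 6.54 ± 0.20, adjusted p = 1.81e-06), while its brighter probe set read 1420 ± 416 against 102 ± 98.3 and just missed (4.31 ± 0.85, adjusted p = 0.0506). As the saline-infused values of the dimmer probe set lay within the noise, the floor largely sets its log2 value. Chgb rose from 516 ± 133 to 5464 ± 1344 (3.41 ± 0.39, adjusted p = 0.0108) and Chga from 2088 ± 42.9 to 10811 ± 2387 (2.35 ± 0.21, adjusted p = 0.00531). Cckbr, through which gastrin acts, rose from 305 ± 68.5 to 890 ± 112 on 1 of its 2 probe sets (1.56 ± 0.22, adjusted p = 0.0213). Sst rose from 6689 ± 1310 to 13735 ± 368 (1.06 ± 0.20, adjusted p = 0.0425).

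With gastrin, 282 probe sets passed, 175 higher and 107 lower, and they named 235 genes. Vtn (2.00 ± 0.26, adjusted p = 0.0167), Ccn3 (1.91 ± 0.18, adjusted p = 0.00637), Resp18 (1.83 ± 0.34, adjusted p = 0.043) and Ppp1r3c (1.61 ± 0.19, adjusted p = 0.0108, 1 of 2 probe sets) rose after having fallen in the saline-infused knockout. The sulfotransferase gene Sult1a1 rose by 1.69 ± 0.24, the cytochrome gene Cyp2b10 by 1.61 ± 0.24 on 2 of its 3 probe sets, the odorant-binding protein gene Obp2a by 1.55 ± 0.19 and the hepcidin gene Hamp2 by 1.53 ± 0.23 on 1 of its 2. Among the falls, Rsad2, an interferon-induced antiviral enzyme, went from 5277 ± 3287 to 960 ± 175 (-2.31 ± 0.39, adjusted p = 0.0346, 2 of 3 probe sets), and Ifih1, a sensor of viral RNA, changed by -1.19 ± 0.22 (adjusted p = 0.0402). Further falls were those of Slurp1 (-1.76 ± 0.34), Ly6d (-1.63 ± 0.24), Sfn (-1.42 ± 0.24), S100a14 (-1.26 ± 0.11, adjusted p = 0.00392) and Serpinb5 (-1.13 ± 0.22, 1 of 3 probe sets). The galectin gene Lgals3 fell from 8914 ± 1214 to 2937 ± 481 (-1.61 ± 0.23, adjusted p = 0.024). Anln, an actin-binding protein of cell division, changed by -1.55 ± 0.28, the heat shock gene Hspa1b by -1.47 ± 0.26 (2 of 3 probe sets), Crybg1 by -1.15 ± 0.20 and the deacetylase gene Aadac by -1.08 ± 0.19. Of these 24 genes, 7 passed whichever array was left out: Hdc, Chga, Chgb, Ccn3, Ppp1r3c, Obp2a and S100a14. Leaving out saline-infused replicate 1, 2 or 3 ended 16, 13 and 15 of the 24 calls, and leaving out gastrin-infused replicate 1, 2 or 3 ended 12, 14 and 12. The highest adjusted p was 0.131, without saline-infused replicate 1. Another probe set was called the same way for 11 of 62 bright called genes with more than one, and 6 had another of opposite sign.

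Of the 25 lists, 10 passed with gastrin, and for all 10 the call was lost with an estimated correlation. The 17 parietal cell genes were higher (median 0.33, adjusted p = 0.000118, and adjusted p = 0.27 with an estimated correlation). Among them 6 rose and 11 did not pass, and 9 were higher and 1 lower adjusted over the list alone. The 6 were Cckbr, Kcnq1 (1.25 ± 0.24, adjusted p = 0.0432), the water channel gene Aqp4 (0.94 ± 0.16, adjusted p = 0.0369, 1 of 2 probe sets), Kcne2 (0.90 ± 0.13, adjusted p = 0.0255), Slc4a2 (0.77 ± 0.13, adjusted p = 0.0332) and Atp4a, from 38737 ± 5321 to 58696 ± 2323 (0.61 ± 0.11, adjusted p = 0.0393). Atp4b read 80483 ± 935 against 59947 ± 4473 and did not pass (0.43 ± 0.09, adjusted p = 0.059). The 11 enterochromaffin-like and secretory granule genes were higher (median 0.49, adjusted p = 6.25e-05, and adjusted p = 0.143 with an estimated correlation). Of these 2 rose, Chga and Chgb, and 9 did not pass, with 5 higher and 1 lower adjusted over the list alone. Scg5, a chaperone of prohormone processing, read 672 ± 130 against 281 ± 36.3 (1.24 ± 0.25, adjusted p = 0.0517). The 24 oxidative phosphorylation genes were also higher (median 0.26, adjusted p = 1.65e-06, and adjusted p = 0.479 with an estimated correlation). None of them passed alone, while 5 were higher adjusted over the list alone.

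The 21 proliferation genes were lower with gastrin (median -0.72, adjusted p = 2.96e-10, and adjusted p = 0.27 with an estimated correlation). Of these 20 lay on the lower side, none passed alone, and 14 were lower adjusted over the list alone. Mki67, a marker of cycling cells, read 735 ± 67.8 against 1850 ± 444 (-1.31 ± 0.33, adjusted p = 0.0936). The ribonucleotide reductase gene Rrm2 read 523 ± 193 against 1461 ± 128 (-1.54 ± 0.35, adjusted p = 0.0707), and Birc5, a protein of chromosome segregation, read 482 ± 52.5 against 1344 ± 248 (-1.47 ± 0.31, adjusted p = 0.0567). The cyclin-dependent kinase gene Cdk1 differed by -1.20 ± 0.32 (adjusted p = 0.107) and Pcna, the replication clamp, by -0.61 ± 0.14 (adjusted p = 0.0742).

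Interferon response genes were lower with gastrin as well (median -1.14, adjusted p = 3.04e-08, and adjusted p = 0.27 with an estimated correlation). Of the 15, Gbp2 fell, from 311 ± 155 to 76.3 ± 19.9, under the noise level, at least 3.10-fold (adjusted p = 0.0388), and 14 did not pass, and 12 were lower adjusted over the list alone. Ifit1 read 413 ± 142 against 2590 ± 2173 (-2.39 ± 0.56, adjusted p = 0.0766), Ifit3 read 121 ± 58.2 against 697 ± 579 (-2.33 ± 0.54, adjusted p = 0.0766), Usp18 differed by -1.70 ± 0.37 (adjusted p = 0.0645) and Irgm1 by -1.40 ± 0.30 (adjusted p = 0.0613). Without saline-infused replicate 1 the list's median was -0.68 (adjusted p = 6.03e-08). The 15 antigen presentation genes were lower too (median -0.41, adjusted p = 1.05e-05, and adjusted p = 0.27 with an estimated correlation), with 2 that fell, 13 that did not pass and 5 lower adjusted over the list alone. These 2 were the peptide transporter gene Tap1 (-1.0 ± 0.19, adjusted p = 0.0457, 1 of 4 probe sets) and the immunoproteasome gene Psmb8, which read 21 ± 22.1, within the noise, against 181 ± 84.1, at least 1.86-fold lower (adjusted p = 0.0427).

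Of the other lists that passed with gastrin, immediate early and heat shock genes were lower (median -0.46, adjusted p = 0.000207, and adjusted p = 0.347 with an estimated correlation), and only Hspa1b of its 14 genes passed. The immediate early gene Ier3 read 1192 ± 291 against 2031 ± 148 (-0.79 ± 0.22, adjusted p = 0.12). Surface mucous genes were lower (median -0.18, adjusted p = 0.013, and adjusted p = 0.522 with an estimated correlation). Krt20, a keratin of the surface cells, was the member that fell (-1.07 ± 0.18, adjusted p = 0.0329), and 11 did not pass. That call was lost without saline-infused replicate 1 (adjusted p = 0.0523) and saline-infused replicate 2 (adjusted p = 0.0848). Sterol and fatty acid synthesis genes were lower (median -0.21, adjusted p = 0.0416, and adjusted p = 0.64 with an estimated correlation), and none of 16 passed. Msmo1, a sterol oxidase, read 2348 ± 155 against 3404 ± 368 (-0.53 ± 0.13, adjusted p = 0.0815). That call was lost without saline-infused replicate 1 (adjusted p = 0.0669), saline-infused replicate 2 (adjusted p = 0.0848), gastrin-infused replicate 1 (adjusted p = 0.133) and gastrin-infused replicate 2 (adjusted p = 0.0787), and the median was -0.34 without saline-infused replicate 3. Stroma and smooth muscle genes were higher (median 0.69, adjusted p = 0.000118, and adjusted p = 0.358 with an estimated correlation), with all 14 on the higher side and none past the test. Apoa1, an apolipoprotein gene in the intestinal list, rose by 0.83 ± 0.16 (3 of 4 probe sets), and the pancreas list's Pnliprp1 by 0.71 ± 0.12, while neither list passed (adjusted p = 0.599 and 0.488).

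The smooth muscle myosin gene Myh11 read 2483 on gastrin-infused replicate 1 and 369 and 277 on replicates 2 and 3, against 190, 55 and 251 with saline, beside the higher stroma list. Forestomach markers were lower with gastrin without passing (median -0.83, adjusted p = 0.0935), and none of 12 passed. Krt13 read 301, 2822 and 485 with gastrin against 5391, 1171 and 4370 with saline. Leaving out saline-infused replicate 1, 2 or 3 gave 68, 137 and 79 calls in place of 282, and leaving out gastrin-infused replicate 1, 2 or 3 gave 97, 67 and 92. With the Gapdh ratio as a covariate 152 passed. The groups did not overlap for 20.2% of probe sets. Median, mean and test differed in sign for genes reported to respond to gastrin, B and plasma cells, T and natural killer cells, myeloid cells and blood, none of which passed.

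**Figure D2:**
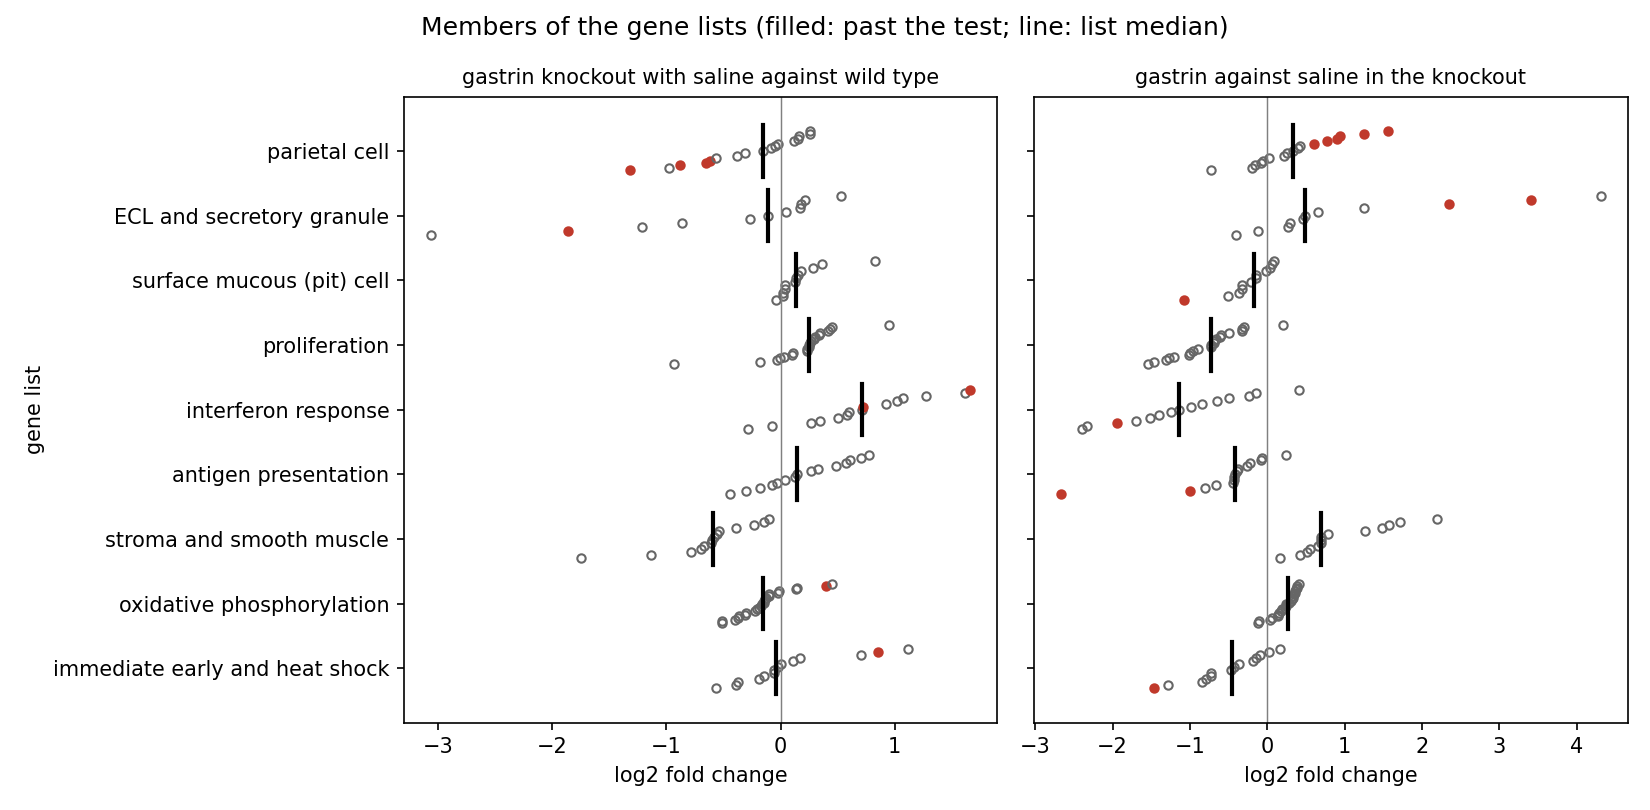
Log2 fold change of the members of 9 gene lists in the saline-infused knockout against wild type and in the gastrin-infused against the saline-infused knockout; points are genes and bars are list medians, and the x axes of the panels differ. The parietal list has medians of -0.15 and 0.33, and the proliferation list 0.25 and -0.72.

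**Figure D3:**
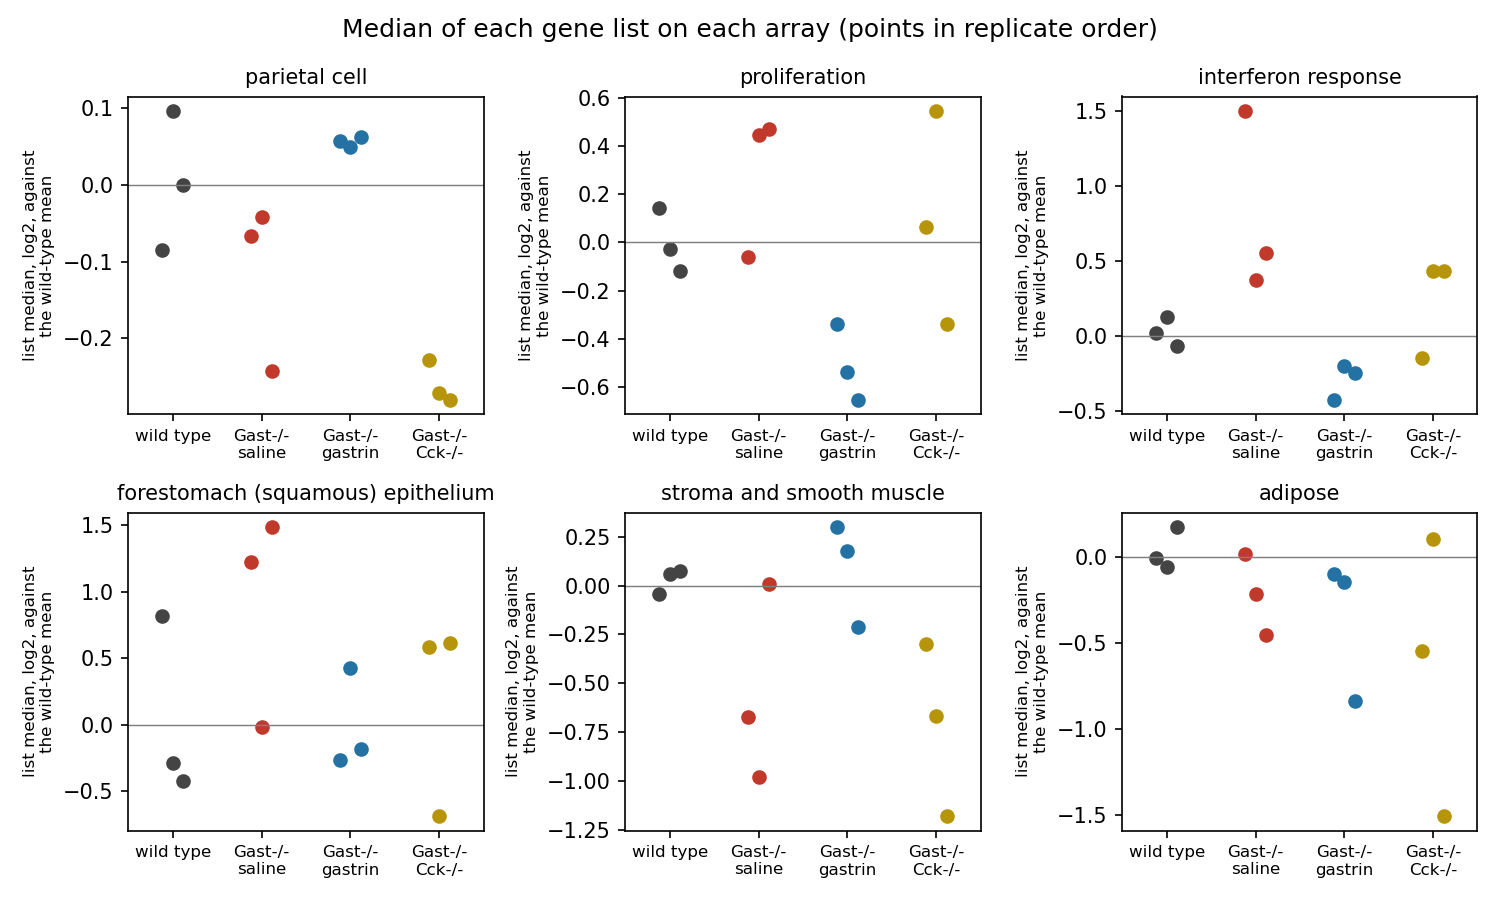
Median over list members of the log2 value relative to the wild-type mean, for parietal, proliferation, interferon, forestomach, stroma and fat lists, on each of the 12 arrays by group. The interferon median is 1.5 on saline-infused replicate 1 and 0.38 and 0.55 on replicates 2 and 3.

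Probe sets that changed in the knockout and changed back with gastrin were counted because both comparisons share the saline-infused arrays. Of the 470 and 282 calls, 137 were opposite in sign, 33 up and then down and 104 down and then up, and 0 had the same sign. Simulated unchanged groups sharing those arrays gave a mean of 0.01, and independent lists of these sizes would share 3.15 in opposite directions, 0.757 up and then down and 2.40 down and then up. The first value leaves out the effects and the second leaves out the shared arrays. The fold changes of the comparisons correlated across probe sets at r = -0.598, where simulation gave -0.498, and genes are not independent replicates. Their covariance was -0.151 against a simulated -0.0768, a difference of -0.0743. The 3 shared arrays could not be divided into independent sets, so part of the excess may come from the shared arrays. The naming rule picked Hdc, Ccn3 and Vtn, together with Slc41a3 (163, -15 and 183 in wild type, saline-infused and gastrin-infused knockout), Pign (167, 7 and 170), Cct3 (107, 6 and 121) and Ndufa10 (142, -38.3 and 93.7). The saline-infused means of Hdc and of these 4 lay within the noise, so that the size of their change and their rank depend on the floor. The rule also picked 3 probe sets without a single gene. Chga, Resp18, Ppp1r3c, Kcnq1 and Sst were opposite in this sense as well, as were Lgals3, Ly6d and Gbp2 from up to down. With the Gapdh ratio as a covariate the count was 20, and without both wild-type arrays of high ratio it was 23. Without wild-type replicate 1, 2 or 3 it was 82, 46 and 51. Without saline-infused replicate 1, 2 or 3 it was 41, 76 and 53, and without gastrin-infused replicate 1, 2 or 3 it was 50, 33 and 47.

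Set against wild type, the gastrin-infused knockout shows how far the infused group stayed from it. Here 25 probe sets passed, 15 higher and 10 lower, naming 22 genes, with 2619 at an unadjusted p under 0.05. With the Gapdh ratio as a covariate 12 passed, and 42 without both wild-type arrays of high ratio. Cyp2b10, a drug- and steroid-oxidising cytochrome, rose most, from 239 ± 12.2 to 1616 ± 287 (2.74 ± 0.24, adjusted p = 0.00493, 2 of 3 probe sets). Hdc was above wild type on the probe set that passed (1514 ± 367 against 531 ± 140, 1.52 ± 0.20, adjusted p = 0.0307), while the brighter one differed by 1.24 ± 0.85 (adjusted p = 0.628). Chgb read 5464 ± 1344 against 1246 ± 590 and did not pass (2.20 ± 0.39, adjusted p = 0.0829), and Cckbr differed by 0.58 ± 0.22 (adjusted p = 0.357).

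Hbb-b2 (1.80 ± 0.25, 1 of 2 probe sets), Snrpd3 (1.49 ± 0.19, 1 of 3), Bco2 (1.34 ± 0.16) and Stk25 (1.17 ± 0.16) were above wild type in both infused groups. Snrpd3 was also higher in the double knockout, which was not described as infused (1.92 ± 0.19, adjusted p = 0.00239). Hbb-b2 was not higher there on this probe set (89.3 ± 20.8 against 138 ± 46.0 in wild type, -0.60 ± 0.25, adjusted p = 0.223). Both infused groups are single gastrin knockouts, and the double knockout also lacks CCK, so infusion and genotype cannot be told apart. Also higher were Ndrg4 (1.63 ± 0.19, both probe sets), the vesicle traffic gene Rab4a (1.48 ± 0.15, adjusted p = 0.0101, 1 of 2), Dock6 (1.28 ± 0.14), the glucocorticoid-responsive gene Fkbp5 (1.02 ± 0.12, 1 of 2), Hnrnpc (0.82 ± 0.11, 1 of 2) and Uqcrc2 (0.62 ± 0.06, adjusted p = 0.00501, 1 of 2). The falls named besides Gast were Ywhaz (-1.64 ± 0.17, 1 of 7 probe sets), the mitochondrial regulator gene Ppargc1a (-1.33 ± 0.17, 1 of 5), Sectm1a (-1.06 ± 0.08, adjusted p = 0.0026), Nmd3 (-0.81 ± 0.11, 1 of 2) and Scaf11 (-0.58 ± 0.08, 1 of 4). Of 17 named genes besides Gast, 4 passed whichever array was left out, Cyp2b10, Rab4a, Sectm1a and Uqcrc2. Leaving out wild-type replicate 1, 2 or 3 ended 9, 6 and 6 of the 17 calls, and leaving out gastrin-infused replicate 1, 2 or 3 ended 9, 13 and 9, with adjusted p up to 0.12 without wild-type replicate 2. Of the counts, 13 probe sets passed without gastrin-infused replicate 2 and 43 without wild-type replicate 3. The groups did not overlap for 16.2% of probe sets. Among 10 bright called genes with more than one probe set, 1 had another called the same way and 6 had another of opposite sign.

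Against wild type 8 lists passed. The proliferation genes were lower (median -0.67, adjusted p = 2.57e-08, and adjusted p = 0.547 with an estimated correlation), with 20 of 21 on the lower side and none past the test. Mki67 read 735 ± 67.8 against 1391 ± 332 (-0.89 ± 0.33, adjusted p = 0.35) and Rrm2 differed by -1.09 ± 0.35 (adjusted p = 0.298). The enterochromaffin-like list was higher (median 0.49, adjusted p = 0.00274, and adjusted p = 0.383 with an estimated correlation), none of 11 passed, and 2 were higher adjusted over the list alone. Immediate early genes were lower (median -0.38, adjusted p = 0.0018, and adjusted p = 0.602 with an estimated correlation), with a median of -0.24 without wild-type replicate 2, and Egr1 read 1202 ± 78.4 against 3003 ± 763 (-1.29 ± 0.49, adjusted p = 0.356). Antigen presentation (median -0.27, adjusted p = 0.0181) and sterol synthesis (median -0.18, adjusted p = 0.0181) were lower, with no member past the test and adjusted p = 0.775 with an estimated correlation for both. Without gastrin-infused replicate 1 both were lost, with adjusted p = 0.241 and 0.083. Interferon genes were lower (median -0.31, adjusted p = 0.0482, and adjusted p = 0.775 with an estimated correlation), and this was lost without wild-type replicate 1, 2 or 3 (adjusted p = 0.0876, 0.0898 and 0.125) and gastrin-infused replicate 1 or 3 (0.215 and 0.187). Blood genes were higher (median 0.42, adjusted p = 0.0327, and adjusted p = 0.547 with an estimated correlation), with 1 of 4, Hbb-b2, past the test, and this was lost without wild-type replicate 3 (adjusted p = 0.125) and gastrin-infused replicate 1 or 3 (0.0559 and 0.12). Oxidative phosphorylation genes were higher by a median of 0.07 (adjusted p = 0.0451, and adjusted p = 0.785 with an estimated correlation), with Uqcrc2 the member that passed. That call was lost without wild-type replicate 1 or 3 (adjusted p = 0.383 and 0.273) and gastrin-infused replicate 1 or 2 (0.083 and 0.116), while the median was 0.12 without wild-type replicate 2 and 0.02 without wild-type replicate 3. The parietal list did not pass (median 0.05, adjusted p = 0.247), and Atp4a read 58696 ± 2323 against 60910 ± 6209. Median, mean and test differed in sign for the chief, other endocrine, B and plasma, myeloid, mast cell, pancreas, intestinal and sex lists, none of which passed.

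The double knockout was set against wild type to see what differs without gastrin and CCK. On 6 of 9 hybridisation controls, compared after the data were seen, all 3 double-knockout arrays lay outside the range of the other 9 arrays, and a batch of arrays cannot be told apart from the group. By the same measure wild type had 1 such control, and the saline-infused and gastrin-infused knockouts had 0 each. A batch is therefore not excluded for any comparison with wild type. Hdc fell on both of its probe sets, the brighter one from 601 ± 164 to 58.7 ± 41.9, at least 7.56-fold (adjusted p = 0.0493), and Chga fell from 7800 ± 2214 to 2583 ± 370 (-1.57 ± 0.21, adjusted p = 0.00833). Pigr rose on both probe sets (1.97 ± 0.27, adjusted p = 0.00833). Ghrl, the ghrelin gene, fell by 0.61 ± 0.10 on the log2 scale (adjusted p = 0.0176), and by 0.31 ± 0.11 after quantile normalization, where it did not pass (adjusted p = 0.14). Chgb read 516 ± 185 against 1246 ± 590 (-1.25 ± 0.39, adjusted p = 0.117) and Sst 11901 ± 2016 against 18659 ± 4457 (-0.64 ± 0.20, adjusted p = 0.111). The enterochromaffin-like list did not pass (median -0.31, adjusted p = 0.0657, 2 of 11 fell and 9 did not pass), and neither did the list of other endocrine cells (median 0.06, adjusted p = 0.468).

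In all, 936 probe sets differed between double knockout and wild type, 457 higher and 479 lower, naming 754 genes. With the Gapdh ratio as a covariate 607 passed, and 76 without both wild-type arrays of high ratio, which leaves 1 wild-type array. The named rises, mostly on 1 of several probe sets, were those of Sfpq (2.10 ± 0.31, 1 of 5), Snrpd3 (1.92 ± 0.19, 1 of 3), Luc7l2 (1.75 ± 0.24, 2 of 5), Srsf1 (1.70 ± 0.28, 1 of 6), Snrnp40 (1.64 ± 0.22, 1 of 2), Fibp (2.60 ± 0.50, 1 of 4), the microtubule-binding gene Mapre2 (2.58 ± 0.24, adjusted p = 0.00178, 1 of 4), Prss44 (2.02 ± 0.44, 1 of 2), the kallikrein gene Klk1 (1.68 ± 0.37, 1 of 3), Zfp280d (1.62 ± 0.35, 1 of 2) and the transcription factor gene Zfhx3 (1.62 ± 0.18, 2 of 3). Among the falls, the acyl-CoA synthetase gene Acsf2 went from 1386 ± 233 to 283 ± 50 (-2.30 ± 0.16, adjusted p = 0.000532). The non-muscle myosin gene Myh9 went from 10184 ± 516 to 2531 ± 281 (-2.01 ± 0.09, adjusted p = 2.25e-05) on a probe set that was 1 of 2 called out of 4. Rarres2, the chemerin gene, read -29 ± 120 against 581 ± 199 on 1 of 3 probe sets, at least 7.46-fold lower (adjusted p = 0.04). The lipid kinase gene Pi4k2a read 36.7 ± 72.1 against 442 ± 110, at least 4.99-fold lower (adjusted p = 0.0296), and the ATP synthase gene Atp5a1 read 71 ± 40.6 against 562 ± 96.6, at least 6.43-fold lower (adjusted p = 0.00877), on 1 of 2 and 1 of 3 probe sets with a mean under the noise level. Ubxn2a (-2.28 ± 0.28, 1 of 2) and Pttg1ip (-1.94 ± 0.33, 1 of 3) fell. The matrix genes Loxl1 (-2.07 ± 0.44) and Sparc (-1.90 ± 0.43, 1 of 2) fell, as did Ly6g2 (-1.69 ± 0.24). Of 340 bright called genes with more than one probe set, 55 had another called the same way and 124 had another of opposite sign. Of 23 named genes besides Gast, 12 passed whichever array was left out: Pigr, Acsf2, Myh9, Mapre2, Zfhx3, Sfpq, Snrpd3, Luc7l2, Snrnp40, Ubxn2a, Atp5a1 and Ly6g2. Leaving out wild-type replicate 1, 2 or 3 ended 11, 9 and 8 of the 23 calls, and leaving out double-knockout replicate 1, 2 or 3 ended 8, 6 and 9, with adjusted p up to 0.131 without wild-type replicate 2. The number of calls was 332, 403 and 407 without wild-type replicate 1, 2 or 3, and 323, 613 and 419 without double-knockout replicate 1, 2 or 3. The groups did not overlap for 23.7% of probe sets.

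Abundant genes of the gastric glands read lower in the double knockout, on arrays whose bright values were lower as a class. The brightest 1% of probe sets had a median change of -0.34 against wild type, with 69 of 227 called lower and 0 higher, and a median of -0.01 after quantile normalization. The pepsinogen gene Pgc read 59505 ± 1785 against 97715 ± 8230 (-0.71 ± 0.07, adjusted p = 0.00326), Atp4b 48755 ± 1850 against 78267 ± 9085 (-0.68 ± 0.09, adjusted p = 0.00802) and the mucin gene Muc5ac 43685 ± 1691 against 69251 ± 6270 (-0.66 ± 0.10, adjusted p = 0.0145). After quantile normalization these changes were -0.14, -0.13 and -0.21 and none passed, and those of Chia1, Tff1, Gkn1 and Gkn2, which had fallen as deposited, changed sign, while Hdc and Chga (-1.52) still passed. The lists that passed were all lower: parietal (median -0.33, adjusted p = 0.000701, 2 of 17 fell, 7 adjusted over the list alone), surface mucous (median -0.48, adjusted p = 0.000701, 5 of 12 fell, 7 adjusted over the list alone) and oxidative phosphorylation (median -0.33, adjusted p = 7.41e-07, 5 of 24 fell, 10 adjusted over the list alone). Each had adjusted p = 0.43 with an estimated correlation. After quantile normalization these 3 lists did not pass (adjusted p = 0.31, 0.974 and 0.386), and the surface mucous median was 0.04. The parietal median was -0.21 without double-knockout replicate 3. Cox6b1, of cytochrome oxidase, was lower under both scalings (-0.79 ± 0.09 as deposited and -0.44 after quantile normalization, adjusted p = 0.0055 and 0.00737). The fourth list, stroma and smooth muscle, was lower under both scalings (median -0.54, adjusted p = 0.00469, and adjusted p = 0.472 with an estimated correlation; adjusted p = 0.021 after quantile normalization). Col1a1, a collagen chain, fell by 1.28 ± 0.24 on the log2 scale (1 of 2 probe sets), and 13 of 14 did not pass. Fat and forestomach markers differed between single arrays of this group: the fat hormone gene Adipoq read 109, 1813 and 5, and Krt13 read 4929, 547 and 4986, on replicates 1, 2 and 3. Median, mean and test differed in sign for the other endocrine, antigen presentation, myeloid, intestinal and endoplasmic reticulum lists, none of which passed.

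**Figure D4:**
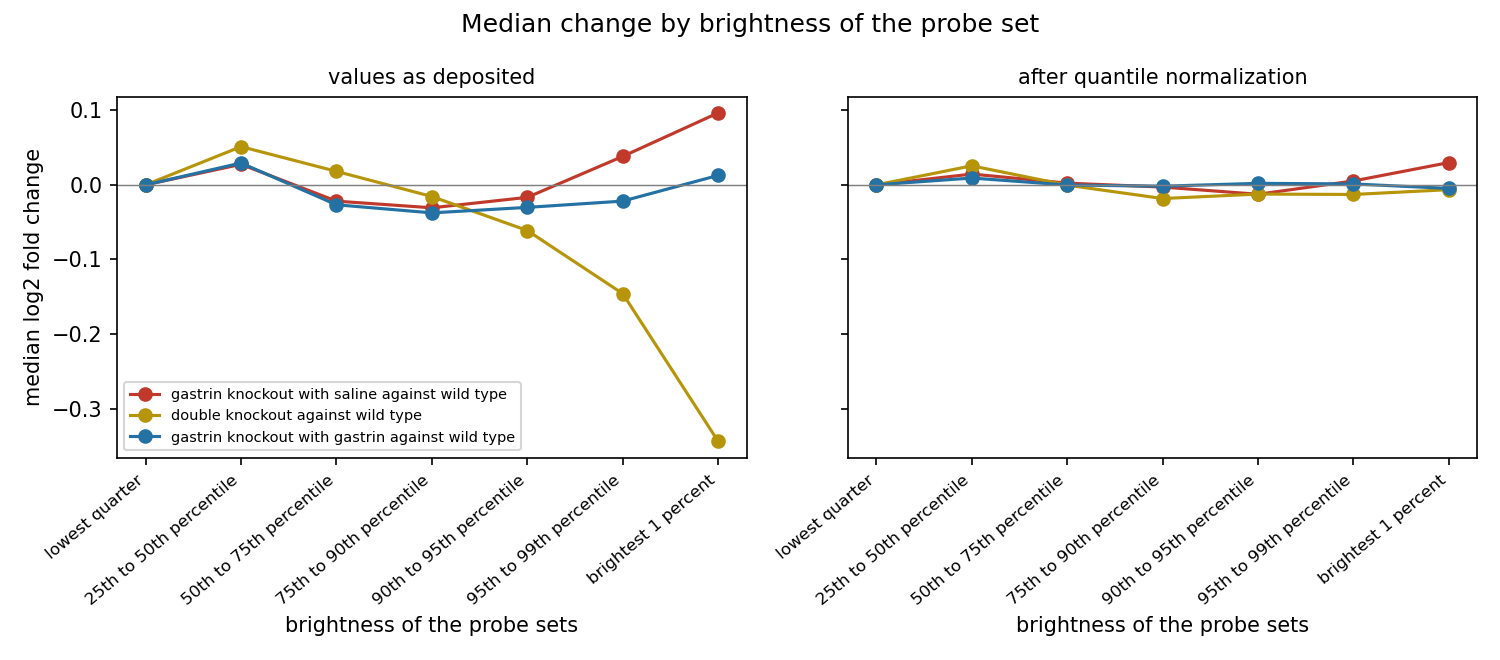
Median log2 fold change in classes of probe sets ordered by brightness, from values as deposited (left) and after quantile normalization (right). Lines are the saline-infused, gastrin-infused and double knockout, each against wild type. The brightest 1% lies at -0.34 in the double knockout against wild type as deposited, and at -0.01 after quantile normalization. Against the saline-infused knockout, which is not drawn, the values for the double knockout are -0.43 and -0.02.

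Probe sets shared by the single and the double knockout, both against wild type, numbered 112, 46 higher and 66 lower, and 5 were called in both with opposite signs. Simulated unchanged groups sharing the wild-type arrays gave a mean of 0, and independent lists of these sizes would share 9.79, 3.23 higher and 6.56 lower. The correlation across probe sets was r = 0.511 against a simulated 0.501, within the simulated maximum of 0.523. The rank correlation was 0.436 against a simulated 0.450, so the correlations show no likeness beyond the shared arrays. The covariance was 0.138 against 0.0774, a difference of 0.0608. Part of the excess in the count and the covariance may come from the shared wild-type arrays, which could not be divided into independent sets. The naming rule picked Hdc, Gast and Pigr, together with probe sets of Slc41a3 (163 in wild type, -15 and 8 in the single and the double knockout), Pign (167, 7 and -20), Gnaz (125, -82 and 2), Gtf2a1l (23.7, 103 and 87.7) and Ugt2b38 (25.3, 90.3 and 91). All of these but Pigr had a mean within the noise in wild type or in both knockouts, so that the size of their change and their rank depend on the floor. The other 2 picked by the rule have no single gene. With the Gapdh ratio as a covariate the count was 19, and without both wild-type arrays of high ratio it was 44. Without wild-type replicate 1, 2 or 3 it was 64, 27 and 64. Without saline-infused replicate 1, 2 or 3 it was 31, 51 and 61, and without double-knockout replicate 1, 2 or 3 it was 48, 65 and 62.

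The last comparison, of the double knockout with the saline-infused gastrin knockout, asked what the further loss of CCK changes, with infusion in 1 arm only. The double-knockout arrays are those that stood apart on 6 of 9 hybridisation controls, so a batch cannot be told apart from the group here either. It gave the largest count, 1352 probe sets, 728 higher and 624 lower, naming 1011 genes, and 911 probe sets passed with the Gapdh ratio as a covariate. Sst was higher in the double knockout (11901 ± 2016 against 6689 ± 1310, 0.83 ± 0.20, adjusted p = 0.0409), as was Kcnq1 (3195 ± 651 against 1678 ± 507, 0.95 ± 0.24, adjusted p = 0.0484). Kit rose from 677 ± 40.5 to 1127 ± 76.6 (0.74 ± 0.08, adjusted p = 0.00311, 1 of 2 probe sets) and the synaptic vesicle gene Syp by 0.51 ± 0.11 on 1 of 2 probe sets. Hbb-b2 fell from 453 ± 47.4 to 89.3 ± 20.8 (-2.36 ± 0.25, adjusted p = 0.00296, 1 of 2).

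The largest rises were those of the transcriptional repressor gene Zbtb20 (from 75.3 ± 51.8, under the noise level, to 647 ± 434, at least 5.60-fold, 1 of 3 probe sets), Zfhx3 (2.18 ± 0.18, adjusted p = 0.00105, 2 of 3), Mapre2 (2.17 ± 0.24, 1 of 4), the transporter gene Slco3a1 (2.16 ± 0.45, 1 of 3 probe sets), Cbfa2t3 (1.85 ± 0.28, 1 of 4) and the signalling kinase gene Irak1 (1.70 ± 0.24, 2 of 4). The next were Ppargc1a (1.56 ± 0.25, 1 of 5 probe sets), Rbm6 (1.55 ± 0.21, 1 of 2), the cell cycle inhibitor gene Cdkn1a (1.53 ± 0.25, 1 of 2), the imprinted noncoding RNA Meg3 (1.52 ± 0.32, 2 of 5), Isoc1 (1.5 ± 0.17, 2 of 4) and the RNA-binding protein gene Tia1 (1.49 ± 0.18, 2 of 3). Falls besides Hbb-b2 were those of Atp5a1 (from 413 ± 19.3 to 71 ± 40.6, at least 4.76-fold, 1 of 3 probe sets), Acsf2 (-2.16 ± 0.16, adjusted p = 0.000915), the interferon-induced gene Mx1 (-2.11 ± 0.44), Pttg1ip (-1.84 ± 0.33, 1 of 3), Myh9 (-1.79 ± 0.09, adjusted p = 9.43e-05, 2 of 4) and Rpl27a (-1.65 ± 0.29, 1 of 2). The protease inhibitor gene Serpina3n changed by -1.65 ± 0.38, the heat shock gene Hspa1a by -1.64 ± 0.35, Bbip1 by -1.51 ± 0.12, Rpf2 by -1.48 ± 0.17 (1 of 3) and the keratin gene Krt7 by -1.48 ± 0.36. Of 455 bright called genes with more than one probe set, 106 had another called the same way and 136 had another of opposite sign. Of the 24 named genes 15 passed whichever array was left out: Zfhx3, Mapre2, Cbfa2t3, Irak1, Ppargc1a, Rbm6, Cdkn1a, Isoc1, Tia1, Acsf2, Atp5a1, Hbb-b2, Myh9, Bbip1 and Rpf2. Leaving out saline-infused replicate 1, 2 or 3 ended 8, 6 and 6 of the 24 calls, and leaving out double-knockout replicate 1, 2 or 3 ended 7, 5 and 5, with adjusted p up to 0.132 without saline-infused replicate 2. The number of calls was 590, 605 and 857 without saline-infused replicate 1, 2 or 3, 496 without double-knockout replicate 1 and 890 without double-knockout replicate 2. The groups did not overlap for 25.2% of probe sets.

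Of the lists, 3 passed and all were lower in the double knockout. Surface mucous genes had a median of -0.50 (adjusted p = 1.5e-06, and adjusted p = 0.617 with an estimated correlation), and 7 of 12 fell, as many as adjusted over the list alone. Krt20 fell under both scalings (-0.99 ± 0.18 as deposited and -0.89 after quantile normalization, adjusted p = 0.0168 and 0.00879), while Muc5ac passed as deposited only (-0.69 ± 0.10, and -0.20 with adjusted p = 0.113 after quantile normalization), and the changes of Tff1 and Ctse turned to above 0 there. The list's median after quantile normalization was -0.08 (adjusted p = 0.32). The brightest 1% of probe sets had a median of -0.43 in this comparison, with 124 called lower and 0 higher. Interferon genes were lower (median -0.45, adjusted p = 0.0185, and adjusted p = 0.789 with an estimated correlation), none of 15 passed, and Ifit3 read 184 ± 57.3 against 697 ± 579 (-1.67 ± 0.54, adjusted p = 0.11). That call was lost without saline-infused replicate 1 (median -0.11, adjusted p = 0.385), without double-knockout replicate 1 (median -0.29, adjusted p = 0.155) and after quantile normalization (adjusted p = 0.0718), and the median was -0.68 without saline-infused replicate 2. Oxidative phosphorylation genes were lower (median -0.11, adjusted p = 0.0185, and adjusted p = 0.789 with an estimated correlation), 4 of 24 fell, and 8 were lower and 1 higher adjusted over the list alone. That call was lost without saline-infused replicate 2 (median -0.05, adjusted p = 0.204) and double-knockout replicate 3 (median -0.03, adjusted p = 0.344), the median was -0.17 without saline-infused replicate 3, and after quantile normalization it was 0.15 (adjusted p = 0.152). Junb fell by 0.91 ± 0.17 on the log2 scale, beside Hspa1a and Hspa1b in the immediate early list, which did not pass (adjusted p = 0.444). Median, mean and test differed in sign for the parietal, chief and mast cell lists, none of which passed. Sprr1a, a squamous envelope protein, fell by 1.04 ± 0.24, and the forestomach list did not pass (median -0.38, adjusted p = 0.378).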

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

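The tests of the patterns below were chosen after the result was seen, except the test of genes flanking Gast and the splits of the arrays, which were planned.

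Control probe sets outside the comparisons differed between groups. A probe set for the 3' end of 18S ribosomal RNA read 251, 236 and 589 in the saline-infused, gastrin-infused and double knockout (means, n = 3), against 76.3 in wild type. In the double knockout the hybridisation controls for the bacterial gene bioB were also above wild type. BioB-3 read 648 against 88.3, BioB-5 731 against 209, and BioB-M 1351 against 211. On the second set of bioB probes, bioB-3 read 934 against 223, bioB-5 1024 against 257 and bioB-M 1535 against 370.

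The brightest probe sets were lower on the double-knockout arrays. Of 213 of the brightest 1% that lie outside the gastric cell lists, 97.2% had a change under 0 against wild type. They are the probe sets of the pattern itself, so this share cannot decide whether bright values lie lower whatever the gene, and that stays open. Their median was -0.33 (SE 0.0155, over probe sets and not arrays), and 207 of the 213 were lower. A loss of surface mucous cells alone would not lower genes outside those cells, so these values argue against it as the whole cause. They are no fresh test, since the median of the whole brightest 1%, -0.34, was known before. The 213 may still hold surface mucous genes that the lists lack. This test was rewritten after its first version was seen. In that first version the 9 bright surface mucous genes had a median of -0.52 and the 3 dimmer ones 0.17 (SE 0.26). On 6 of 9 hybridisation controls all 3 double-knockout values lay outside the range of the other 9 arrays, but batch and group cannot be told apart, so a batch is not excluded. Of these controls, which are not mouse genes, CreX-3 (19317 to 28017 against 28600 to 43256), BioC-3 and BioC-5 (1784 to 2307 against 4435 to 7472) were lower. The dimmer BioB controls were higher, and the ranges of BioDn-3, BioDn-5 and CreX-5 overlapped. Some bright controls were thus lower too, but not all.

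Interferon response genes were higher in the saline-infused knockout than in wild type (median 0.71, adjusted p = 0.000356, and adjusted p = 0.749 with an estimated correlation). The difference was not confined to 1 array: without saline-infused replicate 1 the median was 0.24 (adjusted p = 0.00989), and the arrays' medians of 1.5, 0.38 and 0.55 exceeded the highest in wild type, 0.13. All medians are relative to the wild-type mean, which narrows the wild-type range. The double-knockout arrays had medians of -0.14, 0.43 and 0.43, and the list did not pass in that group (camera adjusted p = 0.274). Arrays at the level of the lower 2 saline-infused ones thus also occurred there. The 33 immune markers had a mean of 0.19 (SE 0.12, over genes) against the interferon list's median of 0.71. Their list medians were 0.27 for T and natural killer cells, -0.12 for B and plasma cells and -0.02 for myeloid cells. These markers rose less than the interferon list. The SE does not cover the spread between arrays, so more immune cells are not excluded. With forestomach markers as a covariate the interferon list's median was 0.65 (adjusted p = 0.00896, and adjusted p = 0.715 with an estimated correlation). The forestomach medians were 1.22, -0.02 and 1.48 on the saline-infused arrays and 0.81, -0.29 and -0.42 in wild type. This covariate partly follows the group, so the fit cannot decide, and forestomach epithelium is not excluded. No biological explanation besides immune cells was tested.

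Strain DNA flanking a targeted gene may carry its own differences. Among the 100 measured neighbours of Gast, 50 on each side, lay 0 of the 91 genes changed in both knockouts, so none of the 91 is itself a gene of that span. Windows had 0.707 such genes on average, and with a count of 0 the share of 10367 windows with as many was 1. Effects of flanking DNA on genes elsewhere, and DNA farther from Gast, were not tested and stay open.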

How the results depend on the processing

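Of the alternatives described here, the covariates and the fits without the double-knockout arrays, the wild-type arrays of high Gapdh ratio, or the arrays with smooth muscle or fat markers were chosen after the data were seen. Of 265 gene values named, Gast and Cck not among them, 212 passed. Over all alternatives 3283 of 4669 kept their direction and their side of the threshold, 1294 became weaker, 83 became stronger and 9 changed sign. When single arrays were left out, 1006 of 1590 stayed the same, 580 became weaker and 4 stronger. Weaker means that a call was lost, which only the 212 that passed could be. Values that had not passed and stayed so count as the same, so these shares overstate how often calls were kept. The cause was not tested unless fewer arrays, fewer genes or a stricter threshold is the alternative itself.

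Quantile normalization gave 746 changed probe sets for the saline-infused knockout against wild type (470 as reported), 593 for gastrin against saline infusion (282) and 51 for the gastrin-infused knockout against wild type (25). It gave 271 opposite (137) and 180 shared (112) probe sets. Lists past the test became 1 for the double knockout against wild type (4) and 0 against the saline-infused knockout (3). In the gastrin-infused knockout against wild type, the calls of blood (adjusted p = 0.0617) and oxidative phosphorylation (adjusted p = 0.069) were lost. The changes that reversed were all in the double knockout: Chia1 0.012, Tff1 0.030, Gkn1 0.040 and Gkn2 0.046 against wild type, and Car2 0.051, Tff1 0.095, Ctse 0.014, Tff2 0.032 and Cox6a1 0.059 against the saline-infused knockout. The cause was not tested.

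Centring on array medians gave 285 changed probe sets in the saline-infused knockout, 79 opposite and 71 shared. With trend and robust moderation the counts were 779 for the saline-infused knockout, 732 with gastrin, 78 for the gastrin-infused knockout against wild type, 315 opposite and 206 shared. A floor of 64 gave 62 for the gastrin-infused knockout against wild type and 171 shared. It reversed Cck, to -0.13 in the saline-infused and 0.077 in the gastrin-infused knockout. The cause was not tested.

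With only bright probe sets, and so fewer genes, 815, 701 and 73 passed in the saline-infused knockout, with gastrin, and in the gastrin-infused knockout against wild type, with 330 opposite, 218 shared, and 1 and 5 lists for the double against the saline-infused knockout and the gastrin-infused knockout against wild type. Gast was removed by that filter. A change of at least 1.5-fold left 610 and 829 for the double knockout against wild type and the saline-infused knockout, and 72 shared. Only the arrays of the 2 groups, hence fewer arrays, gave 22, 20, 43, 208 and 3 changed probe sets for the saline-infused knockout, gastrin against saline, the double knockout against wild type, the double against the saline-infused knockout, and the gastrin-infused knockout against wild type. Gast then did not pass in the saline-infused (-4.35, adjusted p = 0.0857) and gastrin-infused (-5.07, adjusted p = 0.0986) knockouts, which left 1 of 3 comparisons. A plain test per probe set gave 2, 8, 1, 18 and 0, in the same order. With an estimated correlation, lists past the test were 0 in all 5 comparisons. The cause was not tested.

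The replicate numbers do not pair the arrays in most cases: of 15 pairs, 4 correlated best with their own number. All 15 correlations lay between -0.35 and 0.50. Those of the 4 were 0.11 and 0.13 in the saline-infused knockout against wild type, and 0.50 and 0.23 in the double against the saline-infused knockout. The replicate block gave 239 changed probe sets in the saline-infused knockout, 140 with gastrin and 8 for the gastrin-infused knockout against wild type, 70 opposite and 67 shared. The cause was not tested.

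Leaving out 1 array, hence fewer arrays, gave 94 to 285 changed probe sets for the saline-infused knockout, 67 to 137 with gastrin, 323 to 613 for the double knockout against wild type, 496 to 928 against the saline-infused knockout and 13 to 43 for the gastrin-infused knockout against wild type. The lists past the test numbered 2 to 5, 8 to 10, 4 to 5, 2 to 4 and 4 to 7. The opposite probe sets numbered 33 to 82 and the shared 27 to 65. The values of Gast lay between -4.73 and -3.99 in the saline-infused knockout and between -5.45 and -4.77 in the others, but as the knockout values lie within the noise the floor largely sets them. Cck ranged from -0.27 to 1.00, from -1.11 to 0.33 and from -0.067 to 1.20 in the saline-infused, gastrin-infused and double knockout. It reversed at -0.27 and -0.067 without wild-type replicate 1, 0.33 without wild-type replicate 2 and 0.32 without gastrin-infused replicate 2.

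With the Gapdh ratio as a covariate 47, 152, 607 and 12 probe sets changed in the saline-infused knockout, with gastrin, in the double knockout and in the gastrin-infused knockout against wild type, with 20 opposite and 19 shared. With forestomach markers as a covariate the counts were 225 for the saline-infused and 55 for the gastrin-infused knockout against wild type, with 78 opposite. Without the wild-type arrays of high Gapdh ratio they were 77, 76 and 42 for the saline-infused, double and gastrin-infused knockout, with 3 lists for the last, 23 opposite and 44 shared. The remaining wild-type array was assumed to vary like the other groups. Without the arrays with smooth muscle or fat markers they were 92 with gastrin, 459 and 711 for the double knockout against wild type and the saline-infused knockout, and 12 for the gastrin-infused knockout against wild type, with 5 lists for each of the last 2, 44 opposite and 53 shared. Without the double-knockout arrays 175 changed with gastrin and 11 in the gastrin-infused knockout against wild type. The cause was not tested. Genes near the noise level may limit the counts, since 7.57% to 8.47% of the values on an array lay under the floor.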

Other observations

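The 5 genes first given were chosen after their values were seen, while the splits of the arrays were planned tests. Each fell in the saline-infused knockout and rose with gastrin. Ckb, the brain-type creatine kinase that buffers ATP, read 14136, 5948 and 15226 in wild type, saline-infused and gastrin-infused knockout (means, n = 3). Its log2 fold changes were -1.26 ± 0.17 (adjusted p = 0.0138) and then 1.38 ± 0.17 (adjusted p = 0.014). Cox7a1, a subunit of cytochrome oxidase, read 4230, 1939 and 4700 (-1.13 ± 0.13, adjusted p = 0.00898, and 1.28 ± 0.13, adjusted p = 0.00784). Oxct1, which takes ketone bodies into oxidation, changed by -1.21 ± 0.17 (adjusted p = 0.0148, 3 of 4 probe sets) and 1.09 ± 0.17 (adjusted p = 0.0291, 2 of 4), and Hibadh, of valine breakdown, by -1.15 ± 0.15 (adjusted p = 0.0129) and 1.04 ± 0.15 (adjusted p = 0.0247). Igfbp2, which binds insulin-like growth factors, read 3369, 1534 and 3840 (-1.13 ± 0.14 and 1.33 ± 0.14). Cox7a1 and Igfbp2 passed in both comparisons whichever array was left out. Ckb was lost in the knockout without wild-type replicate 2 (adjusted p = 0.0516) and Oxct1 without saline-infused replicate 1 (adjusted p = 0.0527). With gastrin, the call of Oxct1 on this probe set was lost in all 6 fits, with adjusted p up to 0.0901 without gastrin-infused replicate 2, and that of Hibadh in 4 of 6, up to 0.0775 without saline-infused replicate 1.

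The real grouping of the arrays was set beside other splits of the same arrays, which were all possible splits only for the 6 arrays of a comparison. For the 6 arrays of a comparison, 10 splits are too few for a share under 0.05. The real counts of changed probe sets were 470, 282, 936, 1352 and 25 for the saline-infused knockout, gastrin against saline, the double knockout against wild type, the double against the saline-infused knockout, and the gastrin-infused knockout against wild type. The highest among the other splits were 6, 2, 2, 3 and 6, so that 1 split, the real one, was as large in each. For lists past the test the real numbers were 4, 10, 4, 3 and 8 and the highest others 5, 6, 8, 6 and 4, so that 4, 1, 5, 9 and 1 of 10 splits were as large. For the overlaps, the other splits of 9 arrays were drawn at random from those possible. Of 100 splits 1, the real one, reached the 137 opposite and the 112 shared probe sets, and the highest others drawn were 15 and 6. The other splits mix the groups, so that differences between groups count as spread within them. They therefore bear only on the case of no difference among the groups, and not on how much of the overlap comes from shared arrays or a batch.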
